A study of Mus musculus with 24 samples.

How the data were processed

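RNA of differentiated MMH-D3 cells, a mouse hepatocyte line, was measured on 24 single-colour Affymetrix mouse arrays, 1 array per time point. Per the labels' protocols, confluent cells were kept for 14 days in medium with 2% DMSO, renewed on alternate days, then synchronized by a serum shock, which is a pulse of serum that aligns the circadian clocks of cultured cells. Sampling began 12 h after the shock and was repeated every 2 h until 58 h. RNA was purified with a column kit, amplified with Affymetrix's single amplification protocol and labelled with biotin, per the labels' protocols. Nothing in the labels says that the 24 samples came from separate cultures, and no time point had a replicate.

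The authors deposited 1 table of log2 expression values per probe set, made with GCRMA, per the submitters' processing notes. GCRMA corrects the background by probe sequence, normalizes the arrays together and summarizes the probes of a set. The version and settings of GCRMA were not given in the sources used here. The log2 scale was inferred from the values. The lowest value of the table, 2.17, made up 41.2% of all values, so a transcript at it has only an upper bound. Many probe sets also repeated a value of their own above it, and 1048 of the 18526 kept did so on at least 6 arrays, at a median level of 6.27. A repeated value is therefore not by itself a sign of background, and a gene is called dim here where its mean over 8 h lay below 5. The share of values equal to the lowest ranged from 39.4% at 40 h to 42.1% at 46 h, and the median over the kept probe sets from 8.96 at 40 h to 9.14 at 46 h. Each array's median correlation with the other arrays lay between 0.972 and 0.990. The number of arrays limits the precision, and the scatter of the 24 arrays about each fitted curve was the only error available. The p-values therefore rest on the scatter of these arrays about a smooth curve, which may be technical in part. For a gene that moved in a step, this scatter also holds the misfit of the curve. Its standard error and p-value are then no measure of the spread between arrays alone, and a ranking by p favours genes near the fitted shape.

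The table held 45101 probe sets, of which 64 were controls. GEO's platform annotation gave 1 gene symbol for 34958 probe sets, several for 932 and none for 9211. Of those with 1 symbol, 34754 matched a RefSeq gene of the mouse by Entrez ID, which changed 0 symbols. No gene was named from a probe set with several symbols. A gene was represented by its probe set of highest mean log2 value over the 24 arrays. Probe sets with a log2 value of at least 5 in at least 6 of the 24 arrays were kept, which left 18526 probe sets and 9825 genes.

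The main model was fitted with limma 3.58.1 in R 4.3.3 to the log2 values of the 24 arrays. It held an intercept, a linear change over the 46 h and the cosine and sine of a 24 h cycle, with an intensity trend in the variance prior. The moderated F test of cosine and sine gave the 24 h rhythm, and the moderated test of the linear term gave rises and falls. Benjamini-Hochberg adjustment ran over the kept probe sets, with a threshold of 0.05. Amplitudes are the height of the fitted cosine above its mean on the log2 scale. Peaks are hours after serum shock, and only the first is given. Errors are standard errors of the fit. Changes with arrays left out are fitted slopes expressed over the same 46 h. For a step or a plateau they can exceed any change seen between the arrays. Terms for a 12 h cycle, and products of the 24 h terms with an indicator of the arrays from 36 to 58 h, were tested in the same manner in added fits. The latter compared the 24 h terms of the windows from 12 to 34 h and from 36 to 58 h, with 12 arrays in each. The period of clock genes came from a least-squares cosine with a free period and a linear term, with a 95% interval by the F ratio.

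The 24 gene lists and 6 lists of cell type markers were fixed before the data were examined. The rhythmic share of a list was compared with that of all other genes by a one-sided Fisher's exact test, adjusted over the lists. The cosine fit of its mean profile had a permutation test with 100000 shuffles of the times. Trends of lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move on balance one way and does not compare the list with other genes. The genes named were those of the core clock and of polyamine metabolism that were measured, the 12 of largest 24 h amplitude, the 8 of largest rise and the 8 of largest fall among those past the threshold, the 5 of smallest p in the 12 h test and in the window test, and from every other list the 3 of smallest p for rhythm and the 3 for trend. A gene named outside this rule is said to be so. Means over consecutive blocks of 8 h, with 4 arrays each, describe the time course and were chosen after the data were seen.

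The tests were checked on simulated data with the means and scatter of the 18526 kept probe sets. For the 24 h test, 53.7% of cycles with a log2 amplitude of 0.2, 95.5% with 0.4 and 100% with 0.8 were recovered. Of its 224 calls, 8 were of probe sets simulated without any 24 h cycle. The 224 also include probe sets simulated with a cycle in the second window alone, which were not counted as false. For the trend, 59% of changes of 0.5 and 91% of changes of 1 were recovered. For the 12 h test, 59.7% of cycles with an amplitude of 0.2 and 97.0% with 0.8 were recovered. The window test recovered 89.5% of cycles of 0.8 present in the second window alone, the only size simulated for it. The simulated scatter was independent between arrays and held no drift of the kind seen in the data. The alternatives were no filter, a filter at 7, quantile normalization, centring of each array, another variance prior, other drift terms, other periods, a rank test with 1000000 random rankings, minimum folds of 1.5, and leaving out each array or the arrays at 12 to 18 h. Natural cubic splines for drift with 2 to 6 df, with and without an offset between windows in the window test, a period of 48 h and leaving out 44 to 58 h were chosen after the data were seen, as were the counts of rising or falling genes of 3 lists under each alternative, and the changes over 46 h, under each alternative, of core clock and polyamine genes and of genes named after their values were seen. No coordinates are given, because no genome build is named in the files.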

Results

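Genome-wide mRNA levels were followed in MMH-D3 cells, an immortalized mouse hepatocyte line, from 12 to 58 h after a serum shock. The series comprised 24 arrays at 2 h steps with 1 array per time point and no replicates. Expression values are log2 GCRMA values. The stated purpose was a circadian temporal profile of these cells, so the comparisons asked which transcripts cycled with a period of 24 h and which rose or fell over the 46 h of sampling.

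Several transcripts typical of hepatocytes were abundant throughout, while many genes of liver metabolism were below the filter. Of 13 bile acid genes 2 were measured, and of 12 urea cycle and amino acid breakdown genes on the array 5. Over the 24 arrays, Alb (albumin) averaged 15.97 ± 0.245 (SD, n = 24), Rbp4 (retinol-binding protein) 14.29 ± 0.219, Apoa1 13.55 ± 1.04 and the liver transcription factor Hnf4a 11.93 ± 0.197. Of the 15 hepatocyte markers, 10 were measured, while Apoa2, Apoh and F2 lay near the lowest value of the table at 2.17, 2.31 and 2.18. Afp, a fetal liver marker, averaged 11.89, and the bile duct keratins Krt19 and Krt7 averaged 15.44 and 12.53. All 9 fibroblast and stellate cell markers and all 5 endothelial markers were below the filter. Of the 7 macrophage markers, Cd14 (14.79), Cd68 (6.15) and Csf1r (5.36) were measured, and Ptprc and Adgre1 lay near the lowest value at 2.17 and 2.21.

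Core clock genes cycled with a 24 h period. Of 12 measured core clock genes, 8 were called 24 h rhythmic both over all probe sets and adjusted over the list alone. Nr1d1, which encodes the repressor REV-ERB alpha, had the largest amplitude at 1.51 ± 0.13, a peak-to-trough ratio of 8.12, with a first peak at 15.7 h (adjusted p = 4.15e-07). Its relative Nr1d2 peaked at 17.5 h with an amplitude of 1.02 ± 0.09 (adjusted p = 1.18e-06). The period genes Per1 and Per2 peaked at 20.8 and 22.3 h, with amplitudes of 0.41 ± 0.07 and 1.37 ± 0.10 (adjusted p = 0.00717 and 3.41e-08). The cryptochrome Cry2 peaked at 21.1 h (0.46 ± 0.04, adjusted p = 1.43e-06), and Cry1 later, at 26.9 h (1.37 ± 0.11, adjusted p = 2.31e-07). Arntl, which encodes the activator BMAL1, peaked at 30.1 h (0.88 ± 0.12, adjusted p = 0.000769). Bhlhe40 peaked at 18.4 h with the smaller amplitude of 0.26 ± 0.04 (adjusted p = 0.00165). Clock, the partner of BMAL1, had an amplitude of 0.17 ± 0.07 and was not called (adjusted p = 0.257). Rora, Csnk1d and Csnk1e were not called either, with amplitudes of 0.11, 0.08 and 0.03 (adjusted p = 0.343, 0.283 and 0.857). Per3, Npas2, Ciart and Bhlhe41 were below the filter. By the linear term, 7 core clock genes rose and 1 fell over the 46 h, with the same counts adjusted over the list alone. Nr1d1 rose by 1.56 ± 0.31 and Csnk1d fell by 0.30 ± 0.08 (adjusted p = 0.000326 and 0.00335), and camera gave the list an adjusted p of 0.0898. Fry, which does not compare a list with other genes, gave 0.000516. The fall of Csnk1d rested on 1 of 5 probe sets, since the others gave 0.018, 0.18, −0.14 and −0.058, none past the threshold. Clock, counted among the rises at 0.47, gave −0.26 and −0.29 in its other probe sets, and Csnk1e (0.55) gave −0.0046 in another. Of the 7 rises, 1 kept its call without the arrays at 44 to 58 h, a setting chosen after the data were seen, that of Bhlhe40 (0.80 against 0.44), as did the fall of Csnk1d (−0.49). Nr1d2 (−0.31), Clock (−0.23) and Arntl (−0.54) then had the opposite sign, and Nr1d1 (0.78, adjusted p = 0.233), Csnk1e (0.33, adjusted p = 0.188) and Cry2 (0.086, adjusted p = 0.746) were not called. Without the harmonic the rises of Nr1d1 (0.24, adjusted p = 0.808), Cry2 (0.24, adjusted p = 0.415) and Bhlhe40 (0.21, adjusted p = 0.237) were lost, and Nr1d2 gave −0.021. Arntl then rose by 1.55 against 0.77 with it, and without 12 to 18 h the rises of Nr1d2, Clock and Arntl were 1.41, 0.76 and 1.40 and that of Bhlhe40 0.26. Arntl was not called without the 58 h array (0.67, adjusted p = 0.087), nor Arntl and Clock with no filter (adjusted p = 0.0962 and 0.0611). Rora, not called as changed, rose by 0.29 in another probe set (adjusted p = 0.042). The rhythm of Bhlhe40 was not called with no trend (adjusted p = 0.0589), and Clock was called without 44 to 58 h (0.26, adjusted p = 0.0293). With drift as a spline of 5 df, a setting chosen after the data were seen, 0 of the 12 genes were called. With 4 df 5 were called, where the amplitudes of Nr1d1, Cry1 and Arntl were 2.32, 2.57 and 1.39. Splines of that many df can take up a daily cycle by construction, so these losses cannot tell a rhythm from drift.

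**Figure D1:**
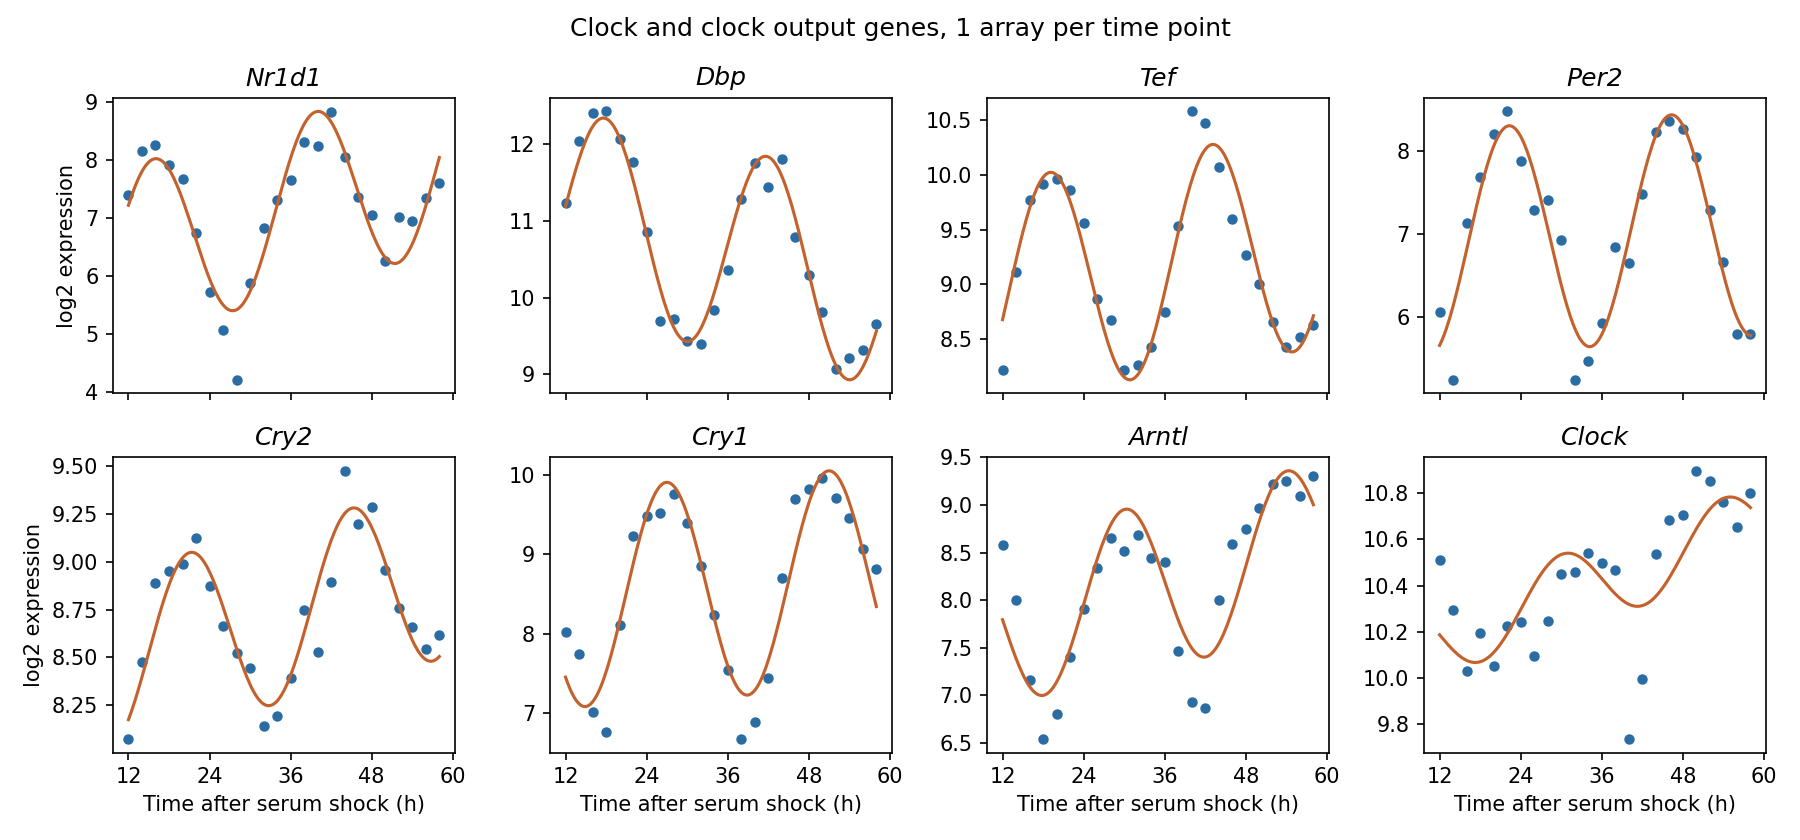
Log2 expression (vertical axis) against hours after serum shock (horizontal axis) for 8 clock and clock output genes; points are single arrays and lines the fitted 24 h cosine plus linear change. Nr1d1 peaked first at 15.7 h and Arntl last at 30.1 h among those of them called rhythmic, and Clock was not called.

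Known outputs of the clock cycled as well. Of 13 measured clock output genes, 6 were called rhythmic, and 9 adjusted over the list alone. Dbp and Tef, which encode PAR-bZIP transcription factors, had amplitudes of 1.33 ± 0.07 and 1.01 ± 0.07 with peaks at 17.8 and 18.99 h (adjusted p = 1.64e-11 and 1.35e-08). Tspan4 peaked at 20.4 h (0.60 ± 0.04, adjusted p = 1.75e-09), and Lonrf3 at 26.6 h (0.68 ± 0.08, adjusted p = 3.30e-05). Core clock genes and clock output genes were the lists with a higher rhythmic share than other genes (Fisher's exact test, one-sided, adjusted p = 3.36e-09 and 7.45e-06). For the other 22 lists the adjusted p was 0.786 or above. The mean profiles of both lists passed the test of a 24 h cycle too, with amplitudes of 0.22 and 0.27 (permutation test, adjusted p = 0.00168 and 0.00024). That of the serum response list also passed (0.12, permutation test, adjusted p = 0.0358). Shuffling the times also removes drift and steps, so this test cannot tell a cycle from these. The serum response profile was −0.34 at 24 h, 0.31 at 46 h and still 0.21 at 58 h. With a free period, the 14 rhythmic genes of the core clock and clock output lists had a median period of 24.1 h. These genes were chosen by the test of a 24 h cycle on the same arrays, which favours periods near 24 h. Dbp gave 24.1 h (95% interval 23.4 to 24.8), Per2 24.1 h (22.9 to 25.3), Nr1d1 24.3 h (23.1 to 25.6) and Cry1 23.2 h (22.1 to 24.4). The intervals of Arntl (20.9 to 23.4), Wee1 (20.3 to 22.9) and Tef (22.2 to 23.7) lay below 24 h, and that of Tsc22d3 (25.8 to 30.4) above it. Wee1 and Tsc22d3 are named here after their values were seen. By the linear term 6 clock output genes rose and 3 fell, or 4 fell adjusted over the list alone. The 3 were Dbp (−0.95 ± 0.16) and, named after their values were seen, the transferrin receptor gene Tfrc (−0.98 ± 0.25) and the cold-inducible Cirbp (−0.62 ± 0.11). The split was 5 and 4 after quantile normalization or centring, and camera gave an adjusted p of 0.774 and fry 0.00951. Dbp and Cirbp kept their calls without the arrays at 44 to 58 h, with changes of −1.55 and −0.945, and Tfrc gave 0.25. Dbp fell by 2.16 without the harmonic, and Tfrc by 1.70 without 12 to 18 h.

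Across the array, 479 of 18526 probe sets were called 24 h rhythmic, standing for 272 of 9825 genes by their representative probe sets. Most had small amplitudes, with a median of 0.19 over the 272 genes. A ratio of at least 2 from peak to trough was reached by 14 genes. Beside clock genes, the largest fitted amplitudes belonged to Lpl (lipoprotein lipase, 0.87 ± 0.19, first peak 33.3 h, adjusted p = 0.0361), Reg4 (0.74 ± 0.12, 15.9 h, adjusted p = 0.00617) and Tdo2 (tryptophan dioxygenase, 0.60 ± 0.13, 34.3 h, adjusted p = 0.033). Among metabolic genes, Dgat2 (triglyceride synthesis) peaked at 18.0 h (0.28 ± 0.06, adjusted p = 0.0248) and Acot1 (acyl-CoA thioesterase) at 31.4 h (0.26 ± 0.03, adjusted p = 0.00021). Egr1 (0.26 ± 0.06, 13.5 h, adjusted p = 0.0317), Ier3 (0.20 ± 0.04, 16.2 h, adjusted p = 0.0334) and Gstm1 (0.25 ± 0.06, 14.3 h, adjusted p = 0.0491) were also called. Lpl was dim, with means below 5 in 4 of the 6 blocks of 8 h and a lowest mean of 3.93, and Reg4 in 1 block (4.69), so the sizes and rank of these amplitudes were not measured. Each of these but Reg4 and Acot1 lost its call when 1 array was left out. The adjusted p was 0.0681 for Lpl and 0.056 for Dgat2 without 44 h, 0.0621 for Tdo2 without 22 h, 0.0781 for Egr1 without 26 h, and 0.0856 for Ier3 and 0.0978 for Gstm1 without 40 h. The same 6 were not called with no filter, and with a spline of 4 df none of the 8 was called. Calls were also lost for Gstm1 (adjusted p = 0.0615) and Ier3 (adjusted p = 0.0555) after centring, Dgat2 with a spline of 3 df (adjusted p = 0.122) and Egr1 with no trend (adjusted p = 0.142). Gstm1 was not called either with 1 variance prior (adjusted p = 0.0623), without 44 to 58 h (adjusted p = 0.109) or in 2 other probe sets. Beyond the core clock, clock output and serum response lists, a gene list held at most 1 rhythmic gene, and adjusted over the list alone at most 2. Cox6c was the 1 gene of oxidative phosphorylation (adjusted p = 0.0782 without 42 h, 0.0909 with no filter, 0.6 with no trend and 0.121 with a spline of 3 df), and cholesterol synthesis, glucose metabolism, hypoxia, acute phase, mitosis, DNA replication, amino acid response and ribosomal protein genes had 0, also adjusted over the list alone. Other settings called some of the 66 named genes that were not called rhythmic, 23 without 12 to 18 h, 23 with a quadratic trend, 18 with a spline of 3 df and 17 without 44 to 58 h. They included, of the amino acid response, Mthfd2 (1.23, adjusted p = 0.00282 without 12 to 18 h), of cholesterol synthesis Fdft1 (0.35, adjusted p = 0.00858 in that setting), and of mitosis Bub1 (1.05, adjusted p = 0.00268 without 44 to 58 h). The 3 h interval from 15 to 18 h held the first peaks of 109 genes, 40.1% of those called. The second peak of such genes falls around the 40 h array, which differed in technical values. Without that array 282 of the 479 probe sets were still called, and its effect on this share was not tested. The size of the rhythmic set depended on the drift term, with 2064 under a quadratic trend. It was 40 with a spline of 4 df, of which 32 were among the 479, and 0 with a spline of 5 df. Splines of that many df can take up a daily cycle by construction, so the low counts cannot tell a rhythm from drift. Leaving out single arrays moved it to 294 (16 h), 219 (24 h), 174 (26 h), 316 (40 h), 310 (46 h), 252 (52 h) and 302 (56 h), while the highest count was 706 without the 18 h array.

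**Figure D2:**
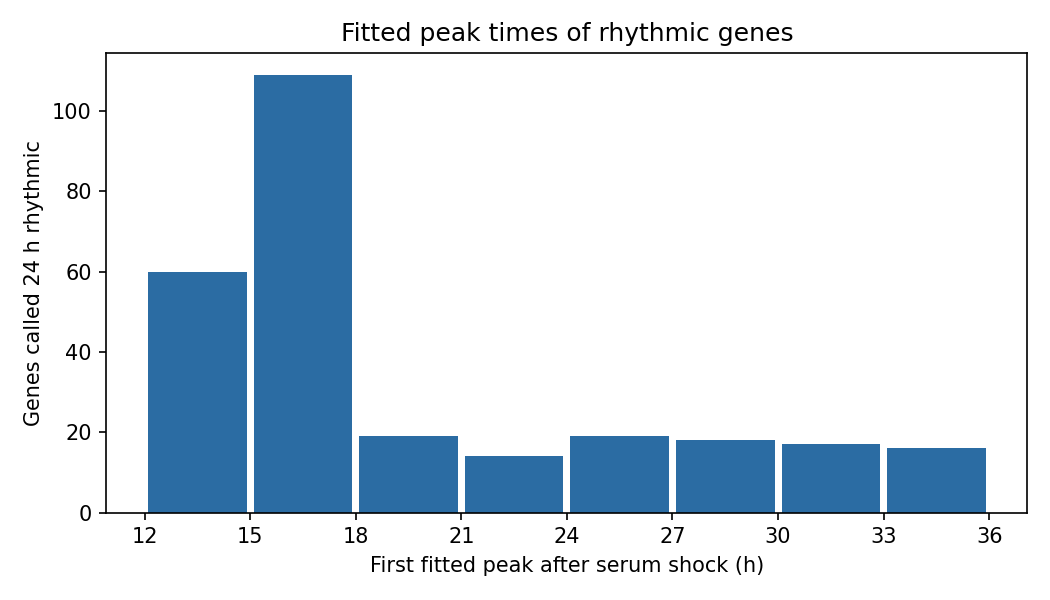
Number of genes called 24 h rhythmic (vertical axis, bars from 0) by the hour of their first fitted peak after serum shock (horizontal axis, 3 h intervals). The interval from 15 to 18 h held 109 of 272 genes.

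No probe set was called for a 12 h cycle with limma, where 0 of 18526 passed and the smallest adjusted p was 0.314. At an unadjusted p under 0.05 there were 406. The smallest p-values belonged to Plekhm3, Tpgs2, Pik3c2g, Tasor2 and Raly, with 12 h amplitudes of 0.34, 0.22, 0.21, 0.16 and 0.41 (unadjusted p = 1.69e-05, 0.000357, 0.000493, 0.000879 and 0.0013). Cry1 and Arntl had 12 h amplitudes of 0.33 and 0.33 (unadjusted p = 0.00403 and 0.0068), which did not pass adjustment.

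Genes of polyamine metabolism were examined as a list that includes Odc1, the rate-limiting enzyme of polyamine synthesis. Of 9 measured genes, 0 were called 24 h rhythmic by limma over all probe sets and 2, Smox and Sat1, adjusted over the list alone. Odc1 had an amplitude of 0.20 ± 0.07 with a first peak at 25.6 h (adjusted p = 0.171), and Smox (spermine oxidase) 0.15 ± 0.04 at 32.5 h (adjusted p = 0.0631). Sat1 and Srm had amplitudes of 0.11 and 0.23 (adjusted p = 0.124 and 0.186), and Sat2, Oaz1, Oaz2, Azin1 and Mtap 0.12, 0.04, 0.05, 0.05 and 0.05. Calls of rhythm appeared in other settings. With a quadratic trend Srm (0.31, adjusted p = 0.000899), Smox (0.17, adjusted p = 0.00669), Odc1 (0.24, adjusted p = 0.0151) and Sat1 (0.11, adjusted p = 0.0423) were called. The same 4 were called without 12 to 18 h (adjusted p = 0.00333, 0.0442, 0.0242 and 0.00682), and Srm, Smox and Odc1 with a spline of 3 df (adjusted p = 0.000933, 0.00213 and 0.0385). Smox was also called with no trend, after quantile normalization and without 44 to 58 h (adjusted p = 0.0422, 0.0459 and 0.00955), and with a spline of 4 df none of the 9 was. Over the 46 h Odc1 rose by 0.60 ± 0.16, Sat1, which acetylates polyamines, by 0.58 ± 0.08, and Mtap by 0.25 ± 0.07 (adjusted p = 0.00452, 3.10e-06 and 0.00796). Oaz1, the antizyme that inhibits ornithine decarboxylase, fell by 0.21 ± 0.05 (adjusted p = 0.00281). Another probe set of Odc1 rose by 1.08. Other probe sets of Mtap gave 0.21, −0.13 and −0.013, and Mtap was not called after centring (0.18, adjusted p = 0.064) or without 12 to 18 h (0.22, adjusted p = 0.0523). When 44 to 58 h was left out Mtap kept its call (0.39), Odc1 gave −0.26, and Sat1 (0.29, adjusted p = 0.0783) and Oaz1 (−0.014, adjusted p = 0.913) were not called. In that setting Srm (−1.09, adjusted p = 0.000257) and Azin1 (−0.67, adjusted p = 6.01e-05) fell and Oaz2 (0.67, adjusted p = 0.00129) and Smox (0.50, adjusted p = 0.00778) rose. Without 12 to 18 h Srm (0.62, adjusted p = 0.00656) and Sat2 (0.52, adjusted p = 0.042) rose, and without the harmonic Smox (0.30, adjusted p = 0.0206) and Sat2 (0.40, adjusted p = 0.0347), while another probe set of Oaz2 rose by 0.36 (adjusted p = 0.0132). Adjusted over the list alone 4 rose and 1 fell, and 2 rose after centring each array. Camera gave an adjusted p of 0.372 and fry 0.00011.

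Non-periodic change was far more common than rhythm. Over the 46 h, 4604 probe sets rose and 3087 fell, and 397 genes rose and 188 fell by a fitted log2 change of at least 1. The largest fitted rises were those of Cdsn (7.005 ± 1.26), Aldh1l2 (6.77 ± 1.08), Chac1 (6.36 ± 1.10), Trib3 (5.72 ± 0.96), Mei4 (5.39 ± 0.85), Car6 (5.18 ± 0.95), Slc7a11 (5.08 ± 0.87) and Angptl6 (4.96 ± 0.82), with adjusted p from 2.74e-05 to 0.000152. Of these, 6 started dim, with means at 12 to 18 h of 2.22 for Cdsn, 2.92 for Aldh1l2, 2.17 for Mei4, 2.21 for Car6, 3.70 for Slc7a11 and 3.35 for Angptl6. Cdsn and Car6 held 1 repeated value on 16 arrays, Slc7a11 on 8, Angptl6 on 7 and Aldh1l2 on 6. The early levels of Cdsn, Mei4 and Car6 lay near the lowest value of the table, and those of Aldh1l2, Slc7a11 and Angptl6 above it but below 5. The sizes of these 6 rises and their order were therefore not measured. None of these 8 rises was called without the arrays at 44 to 58 h, a setting chosen after the data were seen. The fitted change was then 0 for Cdsn, 0.029 for Mei4, 0.0075 for Car6 and 0.014 for Angptl6, and below 0 for Aldh1l2, Chac1, Trib3 and Slc7a11. Without 12 to 18 h the fitted slope over 46 h was 10.57 for Cdsn, 9.56 for Chac1, 8.64 for Trib3, 7.90 for Car6, 7.72 for Slc7a11 and 7.45 for Angptl6. Cdsn itself averaged 2.22 at 12 to 18 h and 8.77 at 52 to 58 h, so such a slope can overstate the rise. The largest fitted falls were those of Prg4 (−5.28 ± 0.61), the complement gene C9 (−5.21 ± 0.29), 2210407C18Rik (−4.26 ± 0.25), the growth factor gene Igf2 (−4.11 ± 0.27), Gsta2 (−4.11 ± 0.35), the alcohol dehydrogenase Adh1 (−3.77 ± 0.57), Mptx1 (−3.56 ± 0.35) and the retinol dehydrogenase Rdh7 (−3.38 ± 0.43), with adjusted p from 5.87e-12 to 1.90e-05. Prg4 and C9 ended dim, with means of 2.86 and 3.61 at 52 to 58 h, so the sizes and order of their falls were not measured either. All 8 falls kept their calls without 44 to 58 h, where the fitted slopes over 46 h were −8.66 for Prg4, −2.29 for Adh1 and −2.24 for Rdh7. That of Prg4 exceeds what its mean of 7.56 at 12 to 18 h and the lowest value of 2.17 allow. Of 122 called changes of genes named in the text or by the rule, 51 kept their call in that setting, 35 lost it and 36 changed sign or became 0. Calls that were kept but moved by over 1.5 times numbered 34 without 12 to 18 h, 27 without 44 to 58 h, 15 in other probe sets and 2 without the harmonic. Risers made up 59.9% of all probe sets called rising or falling, and 47.8% after quantile normalization or 48.0% after centring each array. The balance of directions therefore rested on the scaling.

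All 21 measured amino acid response genes rose, also adjusted over the list alone. This list holds targets of the transcription factor ATF4, which is translated when amino acids are short. Whether amino acids were short here was not measured, and the name of the list is no evidence of it. The mean profile of the list was −0.60 at 42 h, 1.13 at 44 h and 1.55 at 46 h, and stayed between 1.26 and 1.41 from 48 h. Chac1, a glutathione-degrading enzyme, averaged 5.74 ± 0.11 (SD, n = 4 time points) at 36 to 42 h and 11.37 ± 0.19 at 44 to 50 h. Trib3 averaged 6.54 ± 0.12 and 11.27 ± 0.32 in these blocks, Asns (asparagine synthetase, named after its values were seen) 10.36 ± 0.15 and 13.14 ± 0.15, and the cystine transporter Slc7a11 3.62 ± 0.57 and 8.02 ± 0.64. The smallest p-values of the list were those of Ddit4 (1.41 ± 0.07 over 46 h, adjusted p = 3.14e-12), Sesn2 (1.90 ± 0.17, adjusted p = 1.09e-08) and Nars (1.26 ± 0.19, adjusted p = 2.18e-05). The list stood apart from other genes with camera's preset correlation (adjusted p = 3.90e-09) but not with an estimated correlation (adjusted p = 0.432), and fry gave an adjusted p of 2.14e-05. Without the arrays at 44 to 58 h, 2 of the 21 genes rose, Ddit4 (1.42) and Sesn2 (1.15), while Nars gave 0.043 (adjusted p = 0.844) and Asns −1.30. The fitted slope of Asns over 46 h was 4.29 without 12 to 18 h, against 2.61 with all arrays. The larger slope is a line through the step and exceeds the rise between the block means above.

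All 19 measured cholesterol synthesis genes fell, also adjusted over the list alone. Their mean profile was 0.41 at 42 h, −0.27 at 44 h and −0.68 at 46 h. Idi1 (isopentenyl diphosphate isomerase) averaged 12.35 ± 0.07 (SD, n = 4 time points) at 36 to 42 h and 10.70 ± 0.30 at 44 to 50 h, and Insig1, a sterol-regulated gene of the endoplasmic reticulum, 10.46 ± 0.09 and 9.26 ± 0.26. Idi1 and Insig1 are named after their values were seen. Over the 46 h Lss (lanosterol synthase) fell by 1.64 ± 0.17, Mvd by 1.83 ± 0.23 and Hmgcs1 by 1.53 ± 0.20 (adjusted p = 1.15e-07, 1.85e-06 and 2.18e-06). Camera gave an adjusted p of 3.39e-12 with the preset correlation and an adjusted p of 0.401 with an estimated correlation, and fry 2.52e-05. Without the arrays at 44 to 58 h, 3 of the 19 fell, Lss (−0.79), Mvd (−0.87) and Idi1 (−0.49), while Hmgcs1 gave −0.47 (adjusted p = 0.0938) and Insig1 0.31. The fitted slope of Insig1 over 46 h was −2.74 without 12 to 18 h, against −1.71 with all arrays. Both are larger than the fall between its block means above.

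Lipogenic, glycolytic and hypoxia genes included many that fell. In the fatty acid synthesis list 7 of 14 fell and 0 rose, among them Elovl6 (−1.47 ± 0.24) and Srebf1 (−0.87 ± 0.21), which encodes a lipogenic transcription factor. In glucose metabolism 8 of 10 fell and 0 rose, including the phosphofructokinase gene Pfkl (−1.08 ± 0.21) and Pgam1 (−0.51 ± 0.11). In the hypoxia list 7 of 14 fell, including Pdk1 (−1.28 ± 0.26) and Ankrd37 (−1.21 ± 0.25), and 1, the angiogenic factor Vegfa, rose (0.70 ± 0.14). Adjusted over each list alone the falls were 7, 8 and 10, and 2 hypoxia genes rose. Camera's adjusted p with the preset correlation was 0.00727, 0.000639 and 0.00727, and with an estimated correlation the adjusted p was 0.432 for each of the 3 lists. Fry gave 0.00797, 0.00165 and 0.0118. None of these 7 genes was called in that direction without 44 to 58 h, where Elovl6 gave −0.15 (adjusted p = 0.642), Vegfa 0.0035 (adjusted p = 0.99), and Srebf1, Pfkl, Pgam1, Pdk1 and Ankrd37 values above 0. Without 12 to 18 h these 5 gave −1.46, −1.69, −0.84, −2.15 and −1.84, and other probe sets gave −0.82 for Pdk1 and 1.17 for Vegfa.

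Mitosis genes were lowest on the earliest arrays. Their mean profile was −3.24 at 12 h, −3.38 at 14 h and 1.36 at 26 h. Ube2c, an E2 enzyme of the anaphase-promoting complex, averaged 6.77 ± 0.94 (SD, n = 4 time points) at 12 to 18 h and 11.13 ± 0.20 at 28 to 34 h. The kinesin Cenpe averaged 2.72 ± 0.38 and 6.93 ± 0.10 in these blocks, and the kinase Aurka 4.32 ± 1.05 and 8.49 ± 0.21, so both of these started dim. By the linear term over 46 h, 6 of 19 mitosis genes rose and 0 fell, also adjusted over the list alone, and 19 of 19 rose over 12 to 42 h alone, a setting chosen after the data were seen. The count was 0 without the arrays at 12 to 18 h, 2 without the 12 h array, 3 without the 14 h array, 11 without the 26 h array, 10 without the 28 h array and 13 without the 48 h array, and Aurka had a change of 2.31 without the 12 h array (adjusted p = 0.0666) and was not called with no filter (adjusted p = 0.067). Camera gave an adjusted p of 0.0263 with the preset correlation and an adjusted p of 0.642 with an estimated one, and fry 0.0677. Without 44 to 58 h the fitted slopes of Ube2c, Cenpe and Aurka, expressed over 46 h, were 9.33, 8.62 and 8.72, against 3.76, 3.26 and 2.87. These larger slopes exceed the rises between the block means above, since the mean profile was 1.36 at 26 h and 1.18 at 42 h. Another probe set of Cenpe gave 1.92 with all arrays. In the DNA replication list 1 of 19 rose, the licensing factor Cdt1 (0.57 ± 0.16), and 4 fell, the helicase subunits Mcm5 (−0.85 ± 0.21) and Mcm6 (−0.51 ± 0.16), the cyclin Ccne2 (−0.93 ± 0.37) and, named after its values were seen, the thymidylate synthase gene Tyms (−1.13 ± 0.38). Adjusted over the list alone 1 rose and 3 fell. Camera placed the list below other genes with the preset correlation (adjusted p = 0.0263) and gave an adjusted p of 0.629 with an estimated correlation, and fry 0.25. Without the arrays at 44 to 58 h the fitted changes of Mcm5, Mcm6, Ccne2 and Tyms were 0.0105, 0.31, 0.70 and 0.52, and Cdt1 kept its call (1.19). Without 12 to 18 h the fitted falls of the same 4 genes over 46 h were 1.33, 0.96, 2.03 (adjusted p = 5.13e-06) and 2.25 (adjusted p = 5.86e-06). Another probe set of Mcm6 fell by 1.01. Cdt1 was not called without 12 to 18 h (0.21, adjusted p = 0.313). Ccne2 was not called without the 26 h array (−0.81, adjusted p = 0.0944), without the harmonic (−0.66, adjusted p = 0.161), with 1 variance prior (adjusted p = 0.0531) or with no filter (adjusted p = 0.142), nor Tyms, dim at both ends (4.82 and 4.58), with no filter (adjusted p = 0.0628).

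**Figure D3:**
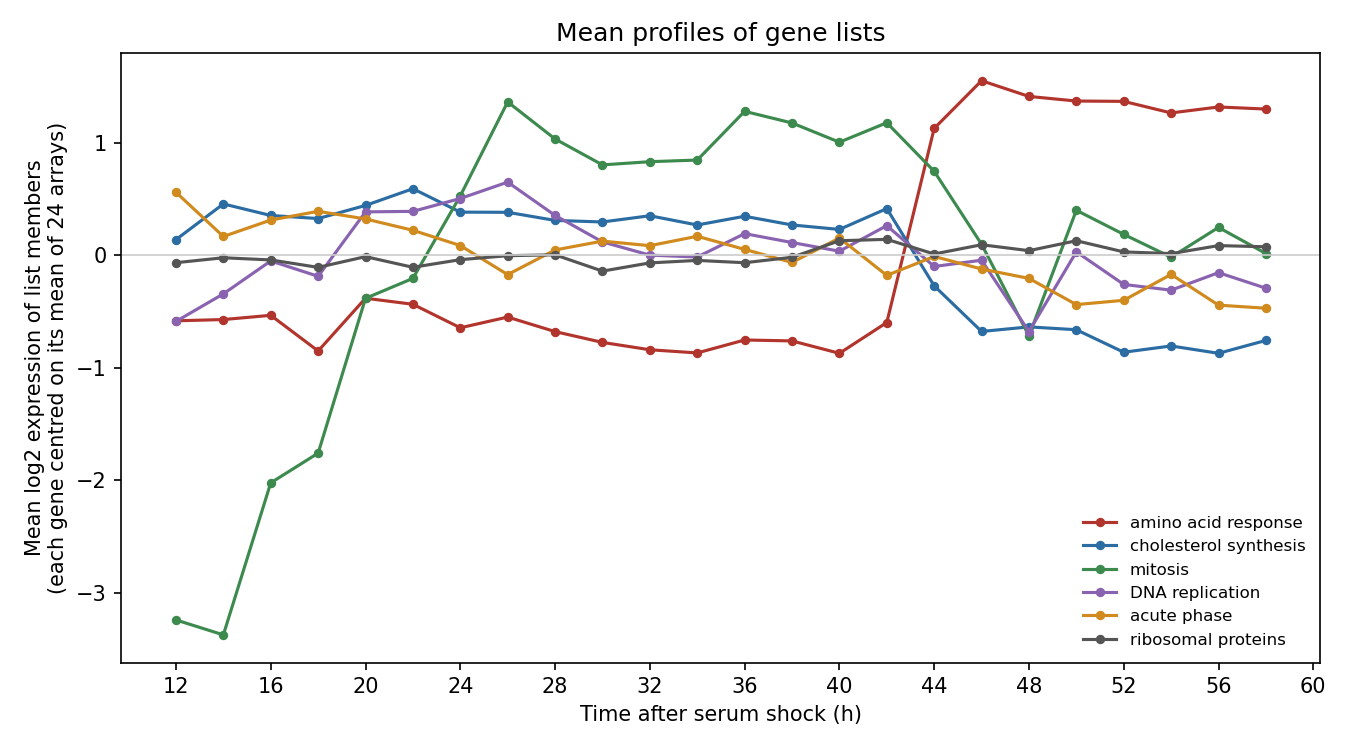
Mean log2 expression of 6 gene lists, each member centred on its mean of 24 arrays (vertical axis), against hours after serum shock (horizontal axis), with 1 array per point. The amino acid response profile was −0.60 at 42 h and 1.55 at 46 h, the cholesterol synthesis profile 0.41 and −0.68, and the mitosis profile −3.24 at 12 h and 1.36 at 26 h.

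Many plasma protein and detoxification genes fell. In the acute phase list 8 of 13 fell, among them the heme carrier Hpx (−1.50 ± 0.10) and the fibrinogen chains Fga (−1.41 ± 0.15) and Fgb (−1.37 ± 0.15), and 0 rose. Adjusted over the list alone 8 fell and 1 rose. In xenobiotic metabolism 6 of 11 fell, including Gsta2 (−4.11 ± 0.35), the sulfotransferase Sult1a1 (−2.39 ± 0.34) and the efflux pump Abcb1a (−1.69 ± 0.30), and 1 rose, the aryl hydrocarbon receptor gene Ahr (0.45 ± 0.13), with the same counts adjusted over the list alone. Camera's adjusted p for these lists was 0.00021 and 0.0221 with the preset correlation, and the adjusted p was 0.228 and 0.432 with an estimated correlation, while fry gave 2.59e-07 and 0.000471. Among hepatocyte markers 3 fell and 2 rose, against 4 and 2 adjusted over the list alone, and 4 and 1 after quantile normalization or centring each array. Apoa1 fell by 2.54 ± 0.42, Ttr by 1.34 ± 0.21 and Alb by 0.34 ± 0.13 (adjusted p = 5.34e-05, 2.27e-05 and 0.0365), while Rbp4 rose by 0.54 ± 0.11 and Cebpa by 0.26 ± 0.10 (adjusted p = 0.000594 and 0.046). Afp rose by 0.33 ± 0.11 (adjusted p = 0.019) and the bile duct marker Epcam fell by 1.29 ± 0.25 (adjusted p = 0.000267). Igf2, a growth factor gene of fetal liver, fell, as given above. Adjusted over the list alone 2 of 4 bile duct markers fell and 3 were rhythmic, as were 2 hepatocyte markers, and over all probe sets 0 of these markers were called rhythmic by limma and 0 of 3 macrophage markers rose or fell, though 1 fell after quantile normalization. With 44 to 58 h left out Hpx, Fga, Fgb, Gsta2, Abcb1a (−2.58), Ahr (0.73), Epcam and Igf2 kept their calls. Sult1a1 (−0.41), Apoa1 (−1.07), Ttr (−0.23), Rbp4 (0.028), Cebpa (0.083) and Afp (0.16) were then not called (adjusted p = 0.213, 0.111, 0.408, 0.897, 0.732 and 0.54), and Alb gave 0.35. Without 12 to 18 h Alb gave −0.60 and Rbp4 0.87, and another probe set of Afp rose by 0.60. Ahr was not called without 12 to 18 h (0.21, adjusted p = 0.227), nor Alb without the 58 h array (−0.29, adjusted p = 0.106). Cebpa was not called without the 44 h array (0.21, adjusted p = 0.0987), after quantile normalization or centring, or without the harmonic, nor were Alb, Cebpa and Afp with no filter. Ahr and these markers are named after their values were seen.

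Ribosomal protein genes rose by small amounts, in 8 of 13 measured (9 adjusted over the list alone), such as Rps19 (0.47 ± 0.06) and Rpl10a (0.27 ± 0.04), and in 6 of 13 after centring each array. The adjusted p of camera was 0.00941 with the preset correlation, and the adjusted p was 0.432 with an estimated correlation and 0.000113 with fry. In the serum response and immediate early list 12 of 20 rose, including Fos (1.18 ± 0.15), Junb (0.66 ± 0.10) and Klf4 (0.58 ± 0.09), and 1 fell, Ccn1 (−0.56 ± 0.14), named after its values were seen. These counts were the same adjusted over the list alone, while 2 genes of the list were called rhythmic, and 7 over the list alone. The split was 11 and 2 after quantile normalization or centring, and without 44 to 58 h Fos and Junb kept their calls, Klf4 was not called (0.11, adjusted p = 0.376) and Ccn1 gave 0.082, against −0.93 without 12 to 18 h. The list had a camera adjusted p of 0.0221, an adjusted p of 0.432 with an estimated correlation and 9.84e-06 with fry. In oxidative phosphorylation 9 of 18 fell and 0 rose, such as Cox5a (−0.46 ± 0.05) and Ndufa9 (−0.51 ± 0.08), with a camera adjusted p of 0.00021, an adjusted p of 0.401 with an estimated correlation and 1.99e-05 with fry. Another probe set of Cox5a fell by 0.29. Rps19, Rpl10a and Cox5a kept their calls without 44 to 58 h, and Ndufa9 did not (−0.28, adjusted p = 0.0633). No list passed camera at 0.05 with an estimated correlation.

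The remaining lists did not pass camera with the preset correlation. Of these, fry gave an adjusted p under the threshold to bile acid (0.00687) and extracellular matrix genes (0.0328). It gave 0.0798 for ribosome biogenesis, 0.741 for oxidative stress, 0.183 for the unfolded protein response, 0.711 for interferon, 0.509 for fatty acid oxidation, 0.248 for heat shock and 0.186 for urea cycle genes. In ribosome biogenesis 9 of 20 rose, such as Npm1 (0.34 ± 0.07), and 1 fell, Bop1 (−0.36 ± 0.13), while 6 rose after quantile normalization or centring (camera adjusted p = 0.113). Bop1 was not called without the 12 h array (−0.29, adjusted p = 0.0824), without 12 to 18 h (−0.15, adjusted p = 0.409) or with no filter (adjusted p = 0.0671). In the oxidative stress list 4 of 11 rose, namely Slc7a11, Hmox1 (1.30 ± 0.17), Sqstm1 (1.03 ± 0.14) and Txnrd1 (0.27 ± 0.08). The 5 that fell were Gsr (−0.65 ± 0.08), Gstm1 (−0.38 ± 0.14), Gclm (−0.43 ± 0.10), Srxn1 (−0.50 ± 0.11) and Txn1 (−0.27 ± 0.06), and camera gave an adjusted p of 0.492. Gstm1 was not called as falling without the 58 h array (−0.35, adjusted p = 0.076) or with no filter (adjusted p = 0.0951). In the unfolded protein response list the stress-induced factor Ddit3 (2.92 ± 0.47), Herpud1 (0.84 ± 0.17) and the chaperone Hspa5 (0.51 ± 0.13) rose. Sdf2l1 (−0.86 ± 0.11), Hsp90b1 (−0.16 ± 0.05), Pdia4 (−0.34 ± 0.10), Calr (−0.54 ± 0.12) and Creld2 (−0.19 ± 0.07) fell among its 16 genes (camera adjusted p = 0.233), Creld2 not without the 12 h array (−0.16, adjusted p = 0.073) or without 12 to 18 h (adjusted p = 0.0581). Pdia4 was not called without 12 to 18 h (−0.11, adjusted p = 0.379), nor Hsp90b1 without the harmonic (−0.080, adjusted p = 0.287). Of 11 interferon response genes Mx1 (3.16 ± 0.42), Cxcl10 (1.98 ± 0.50) and Ifit2 (0.83 ± 0.19) rose and Gbp2 (−1.39 ± 0.10) fell (camera adjusted p = 0.774). The split was 3 and 2 after quantile normalization or centring, and Mx1 and Ifit2 started dim, at 2.86 and 4.16. Ifit2 was not called without 12 to 18 h (0.53, adjusted p = 0.0634). In that setting Ddit3 gave 4.44, Herpud1 1.36, Hspa5 0.90, Cxcl10 3.48, Gstm1 −0.67 and Txn1 −0.43. Without 44 to 58 h Bop1 gave −0.73, Sdf2l1 −0.33, Pdia4 −0.78 and Ifit2 1.31, and other probe sets gave 1.58 for Ddit3 and 0.53 for Npm1.

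Of 11 fatty acid oxidation genes the coactivator gene Ppargc1a (0.57 ± 0.14), the lipid droplet gene Plin2 (0.56 ± 0.08) and Angptl4 (0.56 ± 0.16) rose, and Fabp1 (−3.15 ± 0.71) and Hadhb (−0.51 ± 0.14) fell (camera adjusted p = 0.774). The split of 3 and 2 became 3 and 3 after quantile normalization and 3 and 4 after centring, so its balance rested on the scaling. Of 14 heat shock genes Serpinh1 (0.19 ± 0.06) rose, though not past the threshold after centring, and Dnaja1 (−0.31 ± 0.08), Dnajb1 (−0.22 ± 0.08) and Ahsa1 (−0.29 ± 0.10) fell (camera adjusted p = 0.305). Calls were lost for Serpinh1 without 58 h (0.17, adjusted p = 0.0571), Dnajb1 without 44 h (−0.18, adjusted p = 0.0508) and Ahsa1 without 26 h (−0.24, adjusted p = 0.0641), without 12 to 18 h (−0.21, adjusted p = 0.216) or with no filter (adjusted p = 0.0709). Those of Tdo2 (0.76, adjusted p = 0.115) and Timp1 (0.29, adjusted p = 0.0632) were lost without 12 to 18 h. Of 5 extracellular matrix genes Timp1 (0.37 ± 0.10) rose, and Col4a1 (−0.49 ± 0.11) and Sparc (−0.69 ± 0.19) fell, or 3 fell adjusted over the list alone (camera adjusted p = 0.258). Of 5 urea cycle and amino acid breakdown genes Tdo2 (1.10 ± 0.33) rose, and Glul (−0.61 ± 0.13) and Asl (−0.27 ± 0.07) fell (camera adjusted p = 0.396). Of 13 bile acid genes 2 were measured, and Abcg5 fell by 2.46 ± 0.39 to a dim 3.70 at 52 to 58 h (camera adjusted p = 0.206). Counts of rising and falling genes were otherwise the same adjusted over each list alone. In these lists rhythm was called for Gstm1, Xbp1 (adjusted p = 0.115 without 26 h, 0.0935 with no filter, 0.0604 after centring, 0.071 with 1 variance prior, 0.223 and 0.473 with splines of 3 and 4 df, and 0.0519 without 44 to 58 h, and not called in 3 other probe sets), Acot1 and Tdo2, and adjusted over the list alone for 2 genes each of ribosome biogenesis and the unfolded protein response. The mean and median changes differed in sign for the oxidative stress, interferon, unfolded protein response and urea cycle lists, for which camera pointed down with the median. Values that moved by over 1.5 times without 44 to 58 h were those of Hadhb (−0.98), Glul (−0.97), Tdo2 (2.28) and Timp1 (0.695), and Dnajb1 gave −0.37 without 12 to 18 h. Other probe sets gave 0.96 for Ppargc1a, −0.81 for Dnaja1 and −0.24 for Hadhb. In these lists and the 4 before them the calls kept without 44 to 58 h were those of Bop1, Hmox1, Gsr, Sdf2l1, Pdia4, Mx1, Ifit2, Gbp2, Ppargc1a, Hadhb, Timp1, Tdo2, Glul and Abcg5. The changes of Slc7a11, Ddit3, Herpud1, Hspa5, Calr, Txn1, Gstm1, Cxcl10, Dnaja1, Dnajb1, Serpinh1 and Sparc then had the opposite sign. Npm1 (0.017), Sqstm1 (0.30), Txnrd1 (0.25), Gclm (−0.00035), Srxn1 (−0.21), Creld2 (−0.086), Hsp90b1 (−0.093), Plin2 (0.26), Angptl4 (0.32), Fabp1 (−0.89), Ahsa1 (−0.37), Col4a1 (−0.36) and Asl (−0.21) were not called, with adjusted p from 0.0786 to 0.999. Another probe set of Hspa5 fell by 0.38 (adjusted p = 0.0313), and one of Glul gave 0.058. Other probe sets were not called for Hspa5 (0.36), Txnrd1 (0.20 and 0.041), Hsp90b1 (−0.0199), Serpinh1 (0.083), Dnajb1 (−0.13) and Ppargc1a (0.47 and 0.33). Bop1, Txnrd1, Gclm, Srxn1, Txn1, Hspa5, Pdia4, Calr, Creld2, Ahsa1 and Angptl4 are named after their values were seen.

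The 24 h terms differed between the 12 to 34 h and 36 to 58 h windows for 5569 probe sets. Nr1d2 had an amplitude of 1.37 ± 0.08 in the first window and 0.68 ± 0.08 in the second (adjusted p = 8.68e-05), and Nr1d1 1.95 ± 0.17 and 1.20 ± 0.18 (adjusted p = 0.01). The terms of Per2, Cry1, Cry2, Arntl, Per1 and Bhlhe40 did not differ past the threshold (adjusted p from 0.0887 to 0.833). The smallest p-values belonged to Cxcl10, Nol8, Cdc20, Enpep and Pttg1 (adjusted p = 7.28e-05 for each), of which Cdc20 and Pttg1 act in mitosis. The count was 73 without the arrays at 12 to 18 h, and 882 and 0 with drift as a spline of 2 and 3 df, settings chosen after the data were seen.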

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

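Of the tests in this part, those on array intensity, RNA quality, random lists, drift, the arrays nearest the serum shock, the clock amplitude ratio, the brighter probe sets and the 40 h array were chosen after the result was seen, as were their bounds and the boundary at 44 h, while the shuffled times were chosen before.

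A difference between the windows of 12 to 34 h and 36 to 58 h stood out for 5569 probe sets. Among genes named, the second minus first window amplitude was −0.69 for Nr1d2, −0.75 for Nr1d1, −0.50 for Tdo2, −0.34 for Cdc20, −0.34 for Pttg1 and −0.033 for Dgat2. It was 0.54 for Cxcl10, 0.37 for Nol8, 0.25 for Enpep, 0.56 for Lpl, 0.33 for Gstm1, 0.12 for Egr1 and 0.21 for Ier3. Lpl was dim in 4 of the 6 blocks of 8 h, so the size of its difference was not measured. Each of these passed the test of the difference itself, which also responds to a shift of the peak. With the times shuffled among the arrays, 1 of 100 orders, the real one, gave as many probe sets and the highest other count was 4. A random order of the times would therefore rarely give this count. Shuffling also removes drift and steps, so the test does not tell a change of rhythm from these.

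For this window difference, the arrays at 12 to 18 h are a candidate source, because the count was 73 without them. That design still recovered 75.5% of simulated cycles of 0.8 present in the second window alone. Smaller differences were not simulated, so for those a loss of power cannot be told apart from an effect of these arrays. With drift as a spline of 3 df the count was 0, but that model recovered 37.5% of the same simulated cycles, so drift and a change of rhythm cannot be told apart by it. A weaker clock on the second day cannot be told apart either. The median ratio of second to first window amplitude over the 8 rhythmic core clock genes was 0.932, from 0.496 for Nr1d2 to 1.54 for Bhlhe40. The standard error of the mean ratio over these genes was 0.119. It treats coupled genes on the same arrays as independent, so it does not measure a spread between cultures. Over the 272 rhythmic genes the median of this ratio was 1.11, with 102 of 272 lower in the second window. The design holds 1 culture condition, so no biological explanation beyond the clock ratio was tested.

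The step between 42 and 46 h raised amino acid response genes by a median of 1.74 and changed cholesterol synthesis genes by a median of −1.02 at 44 to 58 h against 28 to 42 h. Normalization that shifts genes by expression level was argued against, because 0 of 10000 random lists matched on mean expression rose as far as the amino acid response list, and 0 of 10000 fell as far as the cholesterol synthesis list. Array intensity or hybridization that acts alike on genes of one expression level was argued against by the same random lists. The amino acid response and cholesterol synthesis lists moved apart by 2.76, against at most 0.42 for 10000 pairs of these random lists. Because the pairs reuse the random lists above, this is not a separate test. The median of all genes shifted by 0.034 and the 9 hybridization control probe sets by −0.11 ± 0.21 (SE). A change of RNA quality was argued against by the small and opposite shifts of the 3′ minus 5′ difference, 0.050 ± 0.028 (SE, 8 against 8 arrays) for actin and −0.041 ± 0.012 for Gapdh. Hybridization that acts by probe sequence was not tested and a change of the culture remains open as a hypothesis, untested because the labels do not separate medium, cell density and handling after the shock.

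Among probe sets called rhythmic, 162 belonged to a gene with a brighter probe set, which need not stand for the main transcript, since levels of different probe sets also reflect probe affinity. The 40 h array as the whole source was argued against, since 102 of the 162 were still called without it. The peaks of the brighter probe sets differed from those called by a median of 1.02 h, as a rhythm shared by probe sets of a gene would give. With a probe set of another gene of like level in place of each, 0 of 10000 random choices came as close, with a median of 5.56 h and a lowest value of 3.90 h, although 82 of the 162 called peaked at 12 to 18 h. The median ratio of amplitudes was 0.668 against 0.305 in the random choices, and 52 of the brighter probe sets were called against at most 16. Probe sets of a gene read the same RNA on the same arrays, so a shared drift, step or array effect would also bring their peaks close. The comparison with other genes therefore cannot tell a shared rhythm from these, and no biological explanation was tested.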

How the results depend on the processing

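Splines for drift, the period of 48 h, the series without 44 to 58 h, the counts for amino acid response, cholesterol synthesis and mitosis genes, and the changes of core clock and polyamine genes and of genes named after their values were seen, were tests chosen after the data were seen. Of the 12 core clock genes, 7 to 9 were called under the alternatives except at periods of 20 h (3) and 48 h (2) and with splines of 4 df (5), 5 df (0) and 6 df (0), and 8 were called with any 1 array left out. The median period of 24.1 h lay between 23.85 and 24.55 h. Its interquartile range over genes was 23.2 to 24.72 h with all arrays and 23.52 to 28.33 h without 44 to 58 h. Signal over background limits the dim genes, since 41.2% of values equal the lowest value, and the cause of each move below was not tested unless the setting itself gives it.

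The 479 rhythmic probe sets became 198 with no filter, 2672 without 12 to 18 h, 2064 with a quadratic trend, 194 by the rank test, 125 at 1.5-fold or more and 1602 without 44 to 58 h. Splines gave 1861 (2 df), 1316 (3 df), 40 (4 df), 0 (5 df) and 0 (6 df), and those of more df can take up a daily cycle by construction. At other periods the count was 29 (20 h), 115 (22 h), 1353 (26 h), 2757 (28 h) and 6828 (48 h), and 0 at each control period of 16, 12, 9.6, 8, 6.9, 6, 5.3 and 4.8 h. Leaving out 1 array gave 174 (26 h) to 706 (18 h). Counts also moved by over 1.5 times to 294 without 16 h, 219 without 24 h, 316 without 40 h, 310 without 46 h, 252 without 52 h and 302 without 56 h. Rising and falling probe sets numbered 1885 and 1096 at 1.5-fold or more, by construction fewer, and rising ones 2657 without 44 to 58 h. The window count was 73 without 12 to 18 h, 882 with a spline of 2 df, 829 with that spline and no window offset, and 0 with splines of 3, 4 and 5 df, with or without the offset. The count of 12 h cycles by limma was 0 (406 at an unadjusted p under 0.05) and 0 also with no filter, the stricter filter, quantile normalization, centring, another prior, without 12 to 18 h, without 44 to 58 h and with any 1 array left out.

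Mitosis genes rising numbered 2 with no filter, 0 without 12 to 18 h, 13 without the harmonic and 19 without 44 to 58 h. Leaving out 1 array gave 2 (12 h) to 13 (48 h), with 3 without 14 h, 11 without 26 h and 10 without 28 h. Without 44 to 58 h, 2 amino acid response genes rose and 3 cholesterol synthesis genes fell.

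Changes over 46 h that changed sign without 44 to 58 h were those of Aldh1l2 (−0.26), Chac1 (−0.86), Trib3 (−0.60), Slc7a11 (−0.41), Srebf1 (0.40), Pfkl (0.12), Pgam1 (0.11), Pdk1 (0.12), Ankrd37 (0.27), Mcm5 (0.0105), Mcm6 (0.31), Dnaja1 (0.034), Serpinh1 (−0.021), Dnajb1 (0.11), Ddit3 (−0.0598), Herpud1 (−0.17), Sparc (0.12), Ncl (−0.20), Nop56 (−0.33), Nr1d2 (−0.31), Clock (−0.23), Arntl (−0.54), Srm (−1.09), Odc1 (−0.26), Alb (0.35), Asns (−1.30), Calr (0.078), Ccn1 (0.082), Ccne2 (0.70), Cxcl10 (−0.62), Gstm1 (0.27), Hspa5 (−0.16), Insig1 (0.31), Tfrc (0.25), Txn1 (0.097) and Tyms (0.52), and that of Cdsn was 0. Nr1d2 was −0.021 without the harmonic. Aurka was −0.33 without 12 to 18 h. Other probe sets gave 0.018 and 0.18 for Csnk1d, −0.0046 for Csnk1e, −0.26 and −0.29 for Clock, −0.13 and −0.013 for Mtap, 0.058 for Glul, −0.36 for Ncl and −0.38 for Hspa5. Of 122 called changes of named genes, the call was lost for 35 without 44 to 58 h, 12 without 12 to 18 h, 11 with no filter, 6 without the harmonic, 3 after centring, 1 after quantile normalization, 1 with another prior, 11 when the array that mattered most was left out, and 0 of 114 with the stricter filter. In other probe sets 70 of 91 results kept the call and 11 lost it. Calls kept without 44 to 58 h numbered 51. Of 66 named genes not called rhythmic, 23 were called without 12 to 18 h, 23 with a quadratic trend, 18 with a spline of 3 df and 17 without 44 to 58 h. Their number was 3 with no trend, 3 after quantile normalization, 1 after centring, 0 with a spline of 4 df, no filter or another prior, and 1 of 61 with the stricter filter. Peaks moved by over 6 h for Tdo2 (amplitude 0.67) and Gstm1 (0.34) with a spline of 4 df and for Cox6c (0.077) in another probe set.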

Other observations

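The tests of replication and division, the settings compared in the next paragraph and the names in it were chosen after the values were seen, while the shuffled times were chosen before.

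Some rhythmic genes outside the fixed lists were called under many settings, although splines of 5 and 6 df gave 0 probe sets. Over the linear model, no trend, a quadratic trend, splines of 3 and 4 df, the rank test, the series without 44 to 58 h and the series without 40 h, 22 probe sets were called under all 8. Beside Nr1d1, Cry1, Dbp, Nr1d2, Tef, Arntl, Lonrf3 and Tspan4 they included Bcor, which encodes a transcriptional corepressor (amplitude 0.32 ± 0.03, first peak 28.2 h), Avpi1 (0.32 ± 0.04, 16.3 h), the annexin Anxa7 (0.29 ± 0.04, 16.7 h) and Pnrc1, a nuclear receptor coactivator gene (0.18 ± 0.02, 30.1 h). Leaving aside the 4 df spline, the rank test and the series without 44 to 58 h, 171 of the 479 probe sets were called under the other 5.

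Serum shock is used to align clocks, and serum also drives cells into the cycle. The hypothesis that cells passed through replication and then division after the shock asks that replication genes peak first. Within 12 to 34 h the median hour of the highest value was 26 for both DNA replication and mitosis genes, a difference of 0 h. Because 15 of 19 replication and 17 of 19 mitosis genes were highest at 26 h, each of 100000 shuffles of the genes also gave 0, so this test could not show an order and the hypothesis stays open. The mean hours, tried after the median, were 25.2 and 26.4, a difference of 1.26 h (permutation test, one-sided, p = 0.0157). It rested on the 4 replication genes that were highest before 26 h and the 2 mitosis genes highest later. With 2 h steps, 1 array per step and genes that are not independent replicates, it does not settle the order.

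Shuffled times bear on whether a random order of the times would give these counts. Shuffling also removes drift and steps, so it cannot tell rhythm from these. For 24 h rhythm, 4 of 100 orders, the real one included, gave as many as 479 probe sets, and the highest other order gave 2113. This points to a structure of the samples, whose cause was not tested. Of the 99 shuffled orders, 95 gave 0. For rising or falling probe sets, 1 of 100 orders gave as many as 7691, and the highest other count was 1538.

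The 40 h array differed in single technical values. Its 18S ribosomal RNA control read 5.32 against 3.86 to 4.62 on the other arrays, its hybridization control mean of 12.65 was the highest of the 24, and its share of values equal to the lowest, 39.4%, the smallest. Its description in the labels also has a different ending from the others. The root mean square change between neighbouring arrays was largest from 40 to 42 h (0.395), from 42 to 44 h (0.384) and from 38 to 40 h (0.365).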
